A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

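The series holds 6 two-colour spotted arrays of budding yeast total RNA, extracted with TRIzol, with 20 µg of total RNA per labelling, per the labels' protocols. The wild type was in the red channel on 3 arrays and the mutant on the other 3. Per the labels, the first array of each orientation carried Cy5 and Cy3 and the other 4 arrays carried Alexa Fluor dyes. The labels describe direct and indirect labelling for arrays named by letters that are not matched to samples, and 2 cultures per strain whose place on the arrays is not given.

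Per the file headers, the slides were read on a GenePix scanner at 635 and 532 nm and the deposited intensity values of spot and local background were made in GenePix Pro 6.1 with no normalization. The deposited percent of saturated pixels was read but not used as a filter, and the deposited flag score of the scanner software marks spots as bad, not found or absent. Each array holds 13824 spots in 24 blocks, with 2 spots per probe, 720 empty spots and 432 other control spots. The headers put the 6 arrays in 2 scan sessions, 4 arrays at 10 µm pixels and 2 at 5 µm. The session of 2 arrays held replicate 1 with the wild type in red and replicate 3 with the mutant in red, so it divides the arrays differently from the dye labels. Gene spots marked bad, not found or absent made up 5.06% to 23.8% of an array. For arrays no counting interval applies, and the number of arrays limits the precision.

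The series value table holds the authors' processed ratios of the same arrays in 6506 rows, and the normalization behind it is not given in the sources used here. Its rows carry no probe name. Blocks of 40 rows were set against the scanner values in the sorted order of the probe names, with the offset of each block taken from the other 5 arrays. The median correlation was above 0 on the arrays with the wild type in red and below 0 on those with the mutant in red, 0.785 to 0.921 in size. The deposited table is therefore wild type over mutant on every array. Its spread was 0.676 to 0.781 times that of log2 ratios, close to the natural log of 2 (0.693), and 2 arrays reach exactly the natural log of 100 (4.61), so the deposited values were read as natural log ratios. The medians of its columns were 0.01, -0.01, -0.04, -0.00108, -0.01 and -0.08, so each array appears centred. It was used only for counts of calls, with the sign turned.

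In R 4.3.3 with limma 3.58.1, spot medians were corrected with normexp (offset 50) and normalised by global loess within each array, with control spots and marked spots at weight 0. Marked spots were left out and the spots of a probe averaged. Of 6250 gene probes, 5763 matched a locus tag of the reference gene table (assembly R64), which gave the symbols, and 487 kept the name in the files. No coordinates are given, since the files name no genome build. The 86 probes whose name ends in -R, which the files do not explain, were kept out of the main comparison. The sign of arrays with the wild type in red was turned, and lmFit and eBayes gave the mutant effect with a dye term for each of the 2 dye systems. A gene was tested where the terms could be estimated with at least 1 residual degree of freedom, which 5879 genes met: 4700 on 6 arrays, 843 on 5 and 336 on 4. Another 371 were not tested. Adjusted p-values are Benjamini-Hochberg over the genes tested, with a threshold of 0.05, and all tests were 2-sided. A spot counted as above background where its median passed the local background by 2 SD.

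Before the data were examined, 25 gene lists, the main model, the alternative settings and the rule for named genes were fixed. Leaving out the -R probes departed from that model, which averaged the probes of a gene. The rule takes MSN2, MSN4 and the 6 W303 loci, the 14 largest falls and 10 largest rises with the same direction on all 6 arrays, and from each list up to 3 members past the threshold, or else up to 2 with the largest size as values. TPS2, PGM1, GSY1, SGA1, PDC1, RPL27B, SOD2, DDR48, STI1, SIS1, FES1, TFA1, DSS4, RPN5 and TEF2 are named outside this rule, and they were chosen after their values were seen. Lists were tested over 4700 genes measured on all arrays with camera at a preset correlation of 0.01, and beside it with camera at an estimated correlation and with fry. Of the 25 lists, 23 had at least 3 such genes, and 9 passed with the preset correlation and 0 with the estimated one. In fry, the stress target, glycogen and a-specific lists had an adjusted p of 0.0129 each. Trehalose had 0.0217, the ribosomal proteins and the other amino acids 0.0413 each, and no other list passed. The median and the camera direction differ in sign for the peroxisomal and the sulfur amino acid lists, and the mean and the median for the W303 loci and the sulfur amino acid list, none of which passed. A planned search for the stress response element in promoters needs a genome sequence and was not run.

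The fit was tested on simulated data made from the residual spreads, dye effects and missing values of the 5879 genes of the mutant comparison, with 67, 67 and 66 genes changed by 3 sizes. It called 41.8% of genes changed 1.5-fold, 71.6% of those changed 2-fold and 95.5% of those changed 4-fold, and 3 of 142 calls were false. With no gene changed it made 0 calls. The simulated values were drawn independently for each gene and array, without shared cultures, correlated genes or a deviating array. These rates may therefore not hold for the real arrays. Alternatives covered the background, the normalization, marked and dim spots, the dye terms, the replicate block, array weights, each array or pair left out, each dye system, the test and the fold threshold. Added after seeing the data were the spot mean as foreground, a dye term per scan session, each scan session alone, the -R probes averaged in, and genes measured on all 6 arrays.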

Results

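Gene expression was compared between the budding yeast strain W303-1A, a laboratory strain of Saccharomyces cerevisiae, and a derivative labelled as lacking MSN2 and MSN4, the genes for the zinc-finger activators of the general stress response. Both strains were grown for 18 h at 30 °C in a zinc-limiting medium supplemented with zinc, washed, and then grown from an optical density of 0.1 to about 0.5 in the same medium without zinc. The comparison therefore asks which transcripts differ when the activators are missing during growth on limiting zinc. No array holds cultures harvested with ample zinc, so whether a difference depends on limiting zinc was not tested. Total RNA of the strains was labelled with different dyes and hybridised together on 6 spotted two-colour arrays, 3 with the wild type in the red channel and 3 with the mutant in the red channel. Of these, 2 arrays carried Cy dyes and 4 carried Alexa Fluor dyes, and both sets held both orientations. The share of gene spots above the local background was between 55.2% and 83.2% in the red channels. In the green channels it was between 69.2% and 90.6%, and 5879 genes could be tested. Control spots with Arabidopsis gene names passed the same cutoff less often than gene spots in every red channel. In green they passed about as often on replicates 1 and 2 with the wild type in red and replicate 3 with the mutant in red. The shares there were 76.6% against 75.6%, 89.1% against 90.6% and 90.6% against 88.4%, so being above background there may not mean yeast transcript. Empty spots passed at 0%, 0.278% and 0.278% in the same green channels, so the cutoff did hold against blank spots. All ratios below are log2 of the RNA labelled mutant over wild type, with the standard error of the fit and n = 6 arrays unless stated. The labels name 2 independently grown cultures per strain, so the 6 arrays shared cultures in a way that is not given. The p-values measure the spread between arrays and may be too small, since a fit with cultures as the unit could not be made.

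The deleted genes were examined first. The MSN2 probe (YMR037C) gave -0.21 ± 0.13 (SE), with an adjusted p of 0.442 and a value below 0 on 4 of 6 arrays. On the arrays with the wild type in red it read -0.55, 0.20 and -0.26, and on those with the mutant in red -0.23, -0.47 and 0.04. It was above background in the channel labelled mutant on 5 arrays. The MSN4 probe (YKL062W) was higher in the RNA labelled mutant by 1.57 ± 0.17 (adjusted p = 0.00694), a 2.96-fold difference, on 6 of 6 arrays. Its values were 2.32, 0.59 and 1.45 with the wild type in red and 1.37, 1.51 and 2.16 with the mutant in red. The MSN4 probe was above background in the channel labelled mutant on all 6 arrays, and the MSN2 signal there was at background on replicate 1 with the wild type in red and 2.62 background SD above it on replicate 3 with the mutant in red. The files do not place the probes within the genes or state which part was removed. The deletion was therefore not checked by these probes, and the strain behind each channel is taken from the labels. The MSN4 call was lost without either of the Cy arrays (1.43, adjusted p = 0.0525).

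In the RNA labelled mutant, 104 genes were lower and 43 were higher at an adjusted p of 0.05, and of these 46 and 2 differed at least 2-fold. The largest falls were those of EGO4 (YNR034W-A), at 15.8-fold, and DDR2 (YOL052C-A), a stress-induced gene known as a target of both activators, at 11.3-fold. HXK1 (YFR053C), which encodes hexokinase 1, was 10.2-fold lower, at -3.35 ± 0.14, although it was above background on 4 of the 6 arrays in the channel labelled mutant, so this fold is uncertain. HSP12 (YFL014W), which encodes a small membrane-associated stress protein, gave -2.81 ± 0.26, a 7.01-fold fall, and its wild-type signal was saturated on 2 arrays, so the fall may be underestimated. RTC3 gave -2.76 ± 0.25, STF2 -2.69 ± 0.19 and RGI1, a gene induced during respiratory growth, -2.51 ± 0.16, with RGI1 also above background on 4 arrays in that channel. CTT1 (YGR088W), the cytosolic catalase T, fell by 1.90 ± 0.22 (adjusted p = 0.0105). The falls and rises of this paragraph were chosen among genes with the same direction on all 6 arrays. TFA1 (-3.40), DSS4 (-2.65) and RPN5 (-2.62) also passed, but each was measured on 4 arrays, of which 3, 3 and 2 were below 0. Rises were smaller. After MSN4, the largest was that of BTN2 (YGR142W), at 1.05 ± 0.11 (adjusted p = 0.00602), a chaperone-related gene of protein aggregate sorting, followed by IZH2 at 0.90, MET14 at 0.89, the Hsp90 gene HSC82 and the Hsp90 cochaperone gene CPR6 at 0.88, HCH1 at 0.86, NCW2 at 0.85, DIA1 at 0.83 and KDX1 at 0.79, all on 6 of 6 arrays.

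**Figure D1:**
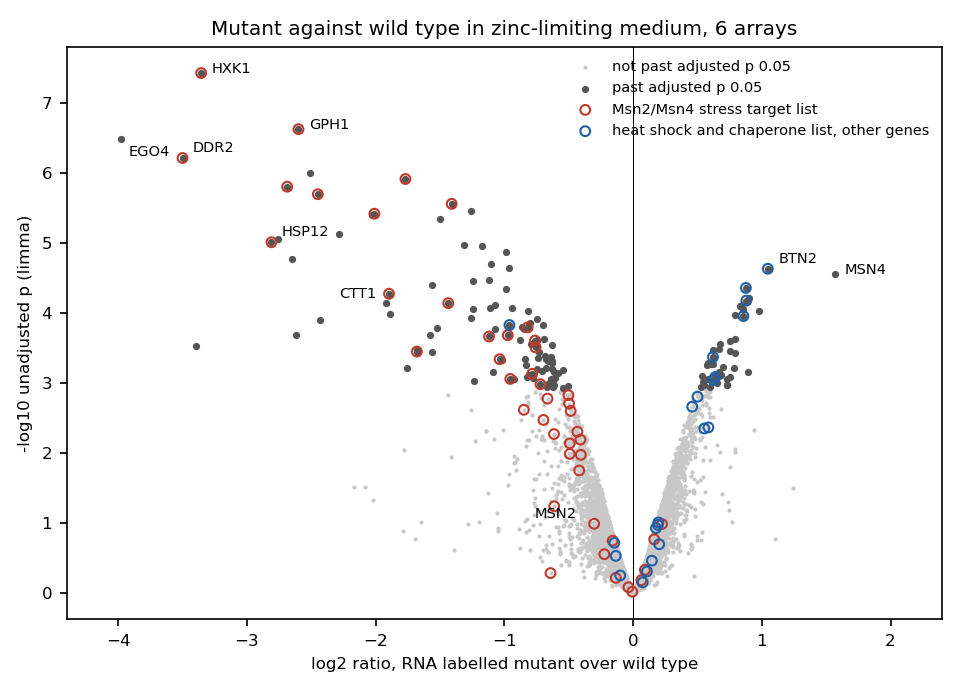
Each point is 1 of 5879 genes, with the log2 ratio of RNA labelled mutant over wild type on the horizontal axis and the -log10 unadjusted limma p on the vertical axis. Dark points are the 104 lower and 43 higher genes past an adjusted p of 0.05, red rings mark the stress target list and blue rings the other heat shock and chaperone genes. The red rings past the threshold all lie left of 0, and MSN4 lies farthest right among the genes past it.

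Of the 104 lower and 43 higher genes, 86 and 36 had the same direction on all 6 arrays. Within the Alexa arrays alone all 104 and all 43 had the direction of the joint fit, as had the 93 lower and 43 higher genes that the Cy arrays measured. The values came from the same arrays as the calls, which favours the same direction. Over all genes measured in both, the effects in Cy and Alexa arrays correlated at r = 0.50, and those in the scan sessions at r = 0.46. Before the dye terms, the turned ratios of 2 arrays correlated at 0.41 to 0.61 within an orientation and at -0.33 to 0.09 between orientations. Over all genes, these ratios thus followed the orientation more than the strains. The dyes, or cultures that went with an orientation, could give this, and the labels do not place the cultures. The Cy and Alexa effects were then compared gene by gene with an interaction term. No gene of 4888 differed at an adjusted p of 0.05 in limma, and 225 had an unadjusted p under 0.05 where 244.4 were expected by chance. The smallest adjusted p was 0.0501, for YPL060C-A. With 2 residual degrees of freedom per gene on 6 arrays, this test does not show that the systems gave equal effects. The arrays were scanned in 2 sessions that divide them differently from the dyes. Between the sessions no gene of 5406 differed in the same test, with 285 at an unadjusted p under 0.05 and 270.3 expected, under the same limit. In the session of 4 arrays all 104 and 43 genes kept their direction, and in the session of 2 arrays 99 of 102 lower and 43 of 43 higher genes that it measured did.

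The number of genes called depended on single arrays. Without either Cy array, 33 genes were lower and 1 was higher. Both of these are the same fit, that of the Alexa arrays only, because the remaining Cy array then carries only its own dye term. Without replicate 2 of the arrays with the mutant in red the counts were 19 and 1, and without replicate 3 of that orientation they were 34 and 10. Without replicate 2 or replicate 3 of the arrays with the wild type in red they were 137 and 50, and 93 and 29. With median centring in place of the intensity-dependent normalisation, 20 genes were lower and 1 was higher, 95.2% of calls on the lower side against 70.7%. Unmoderated statistics called 1 gene lower and 0 higher. Of the 51 genes named by the rule fixed beforehand and past the threshold, 14 stayed past it whichever array was left out, namely EGO4, DDR2, HXK1, HSP12, RTC3, STF2, GPH1, RGI1, PGM2, HXT7, HXT6, GLC3, HSP26 and ARG1. Every one of these was lower, and each of the rises among the 51 genes lost its call without at least 1 of the arrays. With unmoderated statistics the 14 genes lost their calls too.

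Known targets of Msn2 and Msn4 were lower as a group. Of 46 tested members of the fixed stress target list, 21 were lower, 0 were higher and 25 did not pass, and the median ratio was -0.68. Adjusted over the list alone, 34 were lower and 0 higher. The count of 21 fell to 10 without either Cy array, and to 9 and 11 without replicates 2 and 3 of the arrays with the mutant in red. It was 8 with spots marked by the scanner software kept and 0 with unmoderated statistics, and 0 members were higher in each of these. Besides DDR2, HXK1, HSP12 and CTT1, the members that fell included STF2, PGM2 at -2.45 ± 0.18, HSP26, which encodes a small heat shock protein, at -1.77 ± 0.12, SOD2, the mitochondrial manganese superoxide dismutase, at -0.82, and DDR48 at -0.78. The list lay below other genes in camera with the preset correlation (adjusted p = 2.35e-28), and this call was lost with an estimated correlation, at an adjusted p of 0.272. The fry test, which sets the list against no change and not against other genes, gave an adjusted p of 0.0129. The median was -0.85 in the Cy arrays and -0.60 in the Alexa arrays, and -0.59 and -0.75 in the sessions of 4 and 2 arrays.

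Several genes of the storage carbohydrates were lower too. Of 9 tested genes of trehalose metabolism, 4 were lower and 0 higher, namely PGM2, the major phosphoglucomutase, UGP1, which makes UDP-glucose, at -1.56 ± 0.18, TSL1, a subunit of the trehalose synthase complex, at -0.95 ± 0.17 and TPS2, the trehalose phosphatase, at -0.76 ± 0.12. Adjusted over the list alone the counts were 5 and 1, the latter being the minor phosphoglucomutase PGM1 at 0.41. Of 11 tested genes of glycogen metabolism, 3 were lower and 0 higher: glycogen phosphorylase GPH1 at -2.60 ± 0.14, the branching enzyme GLC3 at -2.01 ± 0.16 and the glycogenin GLG1 at -0.80 ± 0.14. Adjusted over the list alone, 7 were lower, while GSY1 stood at -0.02 and SGA1 at 0.02. Enzymes of synthesis and of breakdown were both among these genes. The camera adjusted p was 6.84e-05 for trehalose and 5.33e-07 for glycogen, and with an estimated correlation the adjusted p was 0.305 and 0.272. Both lists hold 5 stress targets, and without those genes the remaining trehalose list gave an adjusted p of 0.333 and the glycogen list 0.0381, both with the preset correlation, the estimated one not having been run for them. GPH1, GLG1 and UGP1 were above background on 3 of the 6 arrays in the channel labelled mutant, and PGM2 and TSL1 on 4, against 6 of 6 in the wild type.

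Heat shock proteins and chaperones moved in both directions. Of 27 tested, 7 were higher, 2 were lower and 18 did not pass, and 11 and 5 passed when adjusted over the list alone. Those that rose were BTN2, a chaperone of the aggregate-sorting pathway, the constitutive Hsp90 gene HSC82, the Hsp90 cochaperones CPR6, HCH1 and STI1 (0.64 ± 0.12), the Hsp40 gene SIS1 (0.62 ± 0.10) and the Hsp70 nucleotide exchange factor FES1 (0.62 ± 0.11, on 5 of 6 arrays). Those that fell were HSP26 and the plasma membrane protein HSP30, at -0.96 ± 0.13. The list median was 0.19, and the camera adjusted p for a rise was 0.0115. With an estimated correlation the adjusted p was 0.446, and fry gave 0.0562.

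The respiratory and sugar genes showed single falls. Of 33 genes of the respiratory chain and ATP synthase, 5 were lower and 0 higher, among them cytochrome c CYC1 at -0.94 ± 0.12, the oxidase subunit COX5B at -0.84 ± 0.14 and QCR8 at -0.74 ± 0.13 (5 of 6 arrays), with 9 lower when adjusted over the list alone. The camera adjusted p was 0.000517, against an adjusted p of 0.446 with an estimated correlation. Of 18 hexose transporter genes, 2 were lower, the high-affinity transporters HXT7 at -2.28 ± 0.20 and HXT6 at -2.03 ± 0.16, and 3 were lower and 1 higher over the list alone. HXT6 and HXT7 are near-identical copies, so their probes may not tell them apart. Of 25 glycolytic and fermentation genes, HXK1, TDH1 (-0.79 ± 0.12) and PDC1 (-0.50) were lower and the glucose-growth hexokinase HXK2 was higher at 0.53 ± 0.10, with 5 and 2 over the list alone. HXK2 lost its call whichever array was left out. Of 18 genes of the TCA cycle list, mitochondrial malate dehydrogenase MDH1 was lower (-0.65 ± 0.12) and the peroxisomal citrate synthase CIT2 higher (0.75 ± 0.12), with 3 and 2 over the list alone. The camera adjusted p was 0.0554 for hexose transport, 0.753 for glycolysis and 0.439 for the TCA cycle.

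Zinc and oxidative stress genes changed at few members. Of 27 tested targets of the zinc-responsive activator Zap1 and other zinc homeostasis genes, 25 did not pass. IZH2, a membrane protein gene induced by Zap1, was higher at 0.90 ± 0.11 (adjusted p = 0.0118), and URA10, a pyrimidine synthesis gene of the same list, was lower at -1.25 ± 0.14 (adjusted p = 0.00791). The list median was 0.11 and the camera adjusted p 0.101, and the list alone also gave 1 lower and 1 higher. Of 32 genes of oxidative stress defence, 4 were lower and 0 higher: CTT1, the glutathione peroxidase GPX1 at -1.26 ± 0.17, sulfiredoxin SRX1 at -1.01 ± 0.17, above background on 4 arrays in the channel labelled mutant, and SOD2. Over the list alone, 8 were lower and 3 higher, and the camera adjusted p was 0.111.

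Iron uptake and ribosomal protein genes were among the rises. Of 25 tested genes of the iron regulon, the metal reductases FRE1 (0.79 ± 0.10) and FRE2 (0.60 ± 0.10) and the siderophore transporter ARN1 (0.75 ± 0.14) were higher and 0 were lower, with 7 higher and 1 lower over the list alone. The camera adjusted p was 0.00219, and the adjusted p was 0.446 with an estimated correlation. Of 134 cytosolic ribosomal protein genes, 4 were higher and 0 lower, and 44 and 2 over the list alone. They were RPL41B (0.98 ± 0.13), RPL41A (0.73 ± 0.13), RPS16A (0.55 ± 0.10) and RPL27B (0.54 ± 0.10), of which RPS16A was higher on 6 arrays and the others on 5, and many members have a near-identical copy, so single genes are uncertain. The list median was 0.25, the camera adjusted p 2.67e-13 and, with an estimated correlation, the adjusted p was 0.423. The median was 0.34 in the scan session of 4 arrays and 0.04 in the session of 2 arrays. None of 82 tested ribosome biogenesis genes passed in limma, over all genes or the list alone, and the median was 0.01. Their largest values, not past the threshold, were -0.68 for CBF5 on 5 arrays and -0.41 for NOP14.

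Amino acid, cell wall and vacuolar genes showed single calls. ARG1, which encodes argininosuccinate synthase, fell by 1.50 ± 0.12 (adjusted p = 0.00211), the only call among 61 other amino acid synthesis genes, of which 10 were lower over the list alone. That list had a camera adjusted p of 0.00153 for a fall, and an adjusted p of 0.423 with an estimated correlation. MET14, which encodes adenylylsulfate kinase, was the only call among 27 sulfur amino acid genes, where the camera adjusted p was 0.987, and over the list alone it was again 1 higher. The daughter-cell wall enzymes SCW11 (0.65 ± 0.12) and CTS1 (0.58 ± 0.10) were higher among 34 cell wall genes, with 4 higher over the list alone and a camera adjusted p of 0.118. Of 22 genes of vacuolar proteolysis and autophagy, the protease inhibitor PBI2 (-0.86 ± 0.12) and the aminopeptidase APE1 (-0.75 ± 0.10) were lower, 3 were lower over the list alone, and the camera adjusted p was 0.0944.

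Apart from the W303 loci, described last, the remaining lists had no member past the threshold over all genes. The 7 a-specific mating genes had a median of 0.30 and a camera adjusted p of 0.0213, against an adjusted p of 0.418 with an estimated correlation, with 3 higher over the list alone. MFA2 stood at 0.42 ± 0.12 and STE2 at 0.40 ± 0.11. The 3 alpha-specific genes were too few on all arrays for a set test, with SAG1 at -0.33 on 5 arrays and STE3 at -0.24. Of the 20 pheromone response genes the largest values were -0.67 for PRM6 on 5 arrays and 0.41 for PRM4 (camera adjusted p = 0.342). Of 17 phosphate regulon genes, PHM8 stood at -0.47 and SPL2 at -0.46 (camera adjusted p = 0.116, with 5 lower and 1 higher over the list alone). Of 23 peroxisomal and fatty acid oxidation genes, SPS19 stood at -0.47 and CTA1 at -0.42, each on 5 arrays (camera adjusted p = 0.938). Of 38 lipid synthesis genes, ERG25 stood at -0.44 and ERG27 at 0.41 (camera adjusted p = 0.0944). In limma, 0 members of the alpha-specific, pheromone response, peroxisomal and lipid lists passed over the list alone.

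Of the 6 loci with auxotrophy or resistance alleles in W303, URA3 was lower by 0.92 ± 0.17 on 5 of 6 arrays (adjusted p = 0.0401) and HIS3 was higher by 0.65 ± 0.12 on 6 of 6 (adjusted p = 0.0438). ADE2 stood at 0.06, CAN1 at 0.23, LEU2 at 0.16 and TRP1 at -0.38, none past the threshold, and over the list alone 2 were lower and 1 higher. The camera adjusted p was 0.967. With each array left out in turn, HIS3 stayed past the threshold in 0 of 6 fits and URA3 in 1.

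**Figure D2:**
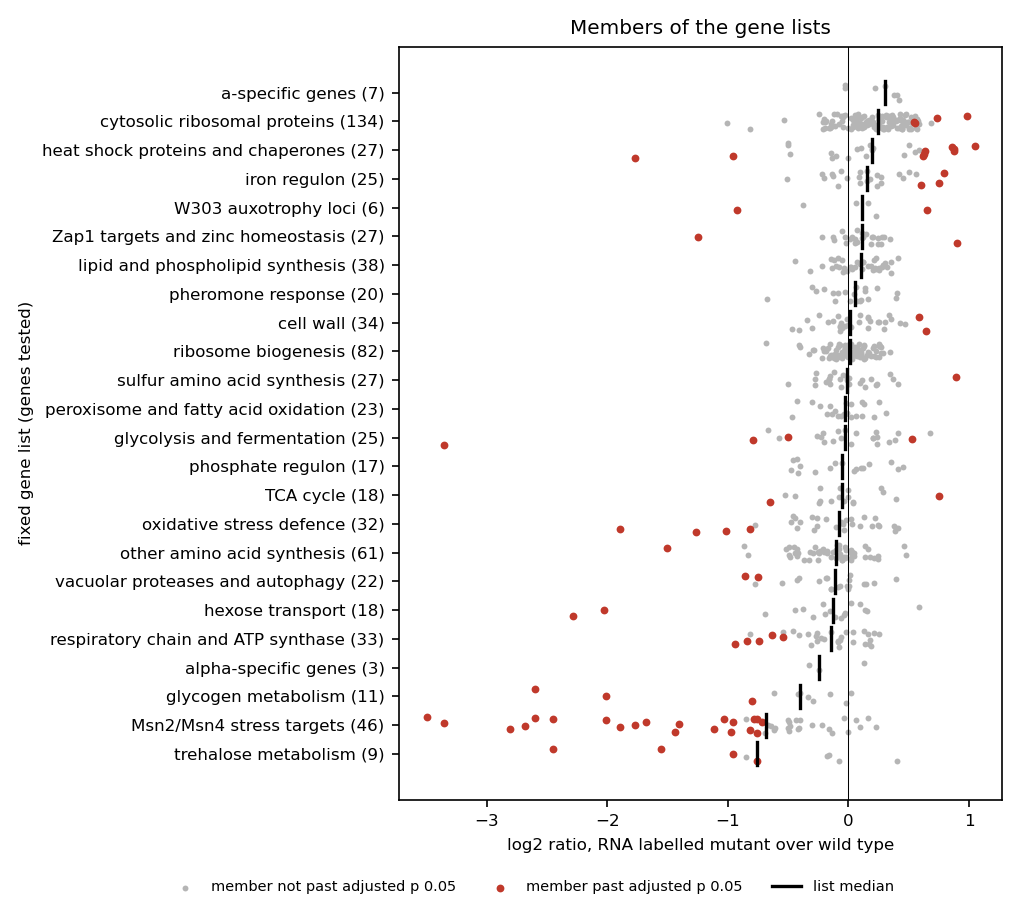
The horizontal axis is the log2 ratio of RNA labelled mutant over wild type and each row on the vertical axis is a gene list fixed beforehand, with the number of genes tested in brackets. Each dot is a gene, red where it passed an adjusted p of 0.05, and the black bar is the list median. The median of the stress target list was -0.68 and that of the ribosomal protein list 0.25.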

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

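The tests of shifts between scan sessions and the reading of the control and -R probes were chosen only after the data had been seen. For the dye systems, the comparison gene by gene was fixed beforehand, and the tests of list shifts were not part of that plan.

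Between the dye systems, 5 gene lists had different shifts with the preset correlation of camera. The median difference, Cy minus Alexa, was -0.29 for the stress targets (adjusted p = 6.73e-07), -0.40 for glycolysis and fermentation (adjusted p = 3.72e-07), -0.41 for trehalose metabolism, -0.31 for hexose transport and -0.26 for the TCA cycle. With an estimated correlation the lowest adjusted p was 0.530. No gene differed between the dye systems at an adjusted p of 0.05 in limma, with 225 at an unadjusted p under 0.05 and 244.4 expected, in a test with 2 residual degrees of freedom per gene. The stress target list had a median below 0 within both systems, at -0.85 and -0.60.

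Between the scan sessions, 5 lists had different shifts with the preset correlation. The median difference, the session of 2 arrays minus the session of 4, was -0.20 for the stress targets (adjusted p = 0.00128), -0.18 for oxidative stress defence (adjusted p = 0.00495), -0.31 for the ribosomal proteins (adjusted p = 8.84e-14), -0.26 for the respiratory chain (adjusted p = 5.02e-06) and -0.31 for the phosphate regulon (adjusted p = 0.0263). With an estimated correlation the lowest adjusted p was 0.880. No gene differed between the sessions in limma, with 285 at an unadjusted p under 0.05 and 270.3 expected, in a test with as few. LEU2, at 0.16 over all arrays and not past the threshold, was above 0 on each of the 4 arrays of one session and below 0 on both arrays of the other, where it read -0.02 and -0.01.

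Some measurements were left out of the main comparison. The 64 control spots with Arabidopsis gene names were above background on up to 42.2% of spots in the red channel and 90.6% in the green channel. What was hybridised to them is not given in the sources used here, and they were not used for normalisation. Of the 85 tested probes with the suffix -R, 7 passed an adjusted p of 0.05 over those probes alone, 4 lower and 3 higher. Of 84 with a tested gene probe, 67 had the same sign as that probe (r = 0.50), and what the suffix stands for is not given in the sources used here. The -R probe with the lowest adjusted p, that of TEF2, went the other way from its gene probe. It read -1.71 (adjusted p = 0.000167 in limma over those probes), and the gene probe read 0.33, not past the threshold.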

How the results depend on the processing

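The spot mean, the dye term per scan session, the scan session fits, the averaging of -R probes and the restriction to genes on all 6 arrays were chosen only after the data had been seen.

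The counts of 104 lower and 43 higher genes depended on the settings. Lower genes numbered 20 with median centring only, 191 with only probes above background, 15 with marked spots kept, 62 with no dye term, 1 with unmoderated statistics, 46 at 2-fold or more and 59 with the series value table. Scan session 1 alone, with its 4 arrays, gave 32. Higher genes numbered 102 with no background subtraction, 21 with plain subtraction, 28 with normexp at offset 0, 1 with median centring, 136 with only probes above background, 0 with marked spots kept (1.57 for MSN4, adjusted p = 0.0862), 19 with no dye term and 70 with array weights. They numbered 0 with unmoderated statistics, 2 at 2-fold or more, 19 with the series value table, 100 among genes on all 6 arrays and 6 in scan session 1 alone. Apart from these and the array subsets of the next paragraph, the settings kept both counts within 1.5 times.

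Leaving out 1 array gave between 19 and 137 lower genes and between 1 and 50 higher genes. The lowest counts, 19 and 1, came without replicate 2 with the mutant in red, and the highest, 137 and 50, without replicate 2 with the wild type in red. Without replicate 1 in both orientations, 33 were lower and 1 was higher. This is the fit of the Alexa arrays only (33 and 1), and leaving out either Cy array gives it again, since the remaining Cy array then carries only its own dye term. Without replicate 2 in both orientations, 78 were lower and 19 higher, and without replicate 3, 111 and 56. Of the 147 genes, those tested kept their sign in every setting with a test, the series value table aside, where genes are unnamed. In the scan session of 2 arrays, which allows no test, 99 of 102 lower and 43 of 43 higher genes did.

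MSN4 stood at 1.57, and with 1 array left out it ranged from 1.43 without a Cy array, which is the fit of the Alexa arrays only (adjusted p = 0.0525), to 1.73 without replicate 2 with the wild type in red. Its call was also lost with unmoderated statistics (1.57, adjusted p = 0.195) and in scan session 1 alone (1.23, adjusted p = 0.0518), and it stood at 2.24 in the other session.

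Of the lists, 9 passed in camera with the preset correlation, 0 with an estimated correlation and 5 in scan session 1 alone. The stress targets gave an adjusted p of 0.272 with an estimated correlation. No list past the threshold changed direction in any setting. Of the 14 lists not past it, 7 passed in some of 31 other settings: hexose transport in 13 (lowest adjusted p = 0.00656), lipid synthesis in 6 (0.0124), Zap1 targets in 5 (0.0314), oxidative stress in 4 (0.0144), the phosphate regulon in 3 (0.0354), vacuolar proteolysis in 3 (0.0126) and the cell wall in 1 (0.0479). Their results in the report depend on the setting.

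Deviations from the mean of an orientation's 3 arrays correlated at 0.05, -0.16 and -0.14 between same-numbered arrays. The highest correlations, between differently numbered arrays, were 0.19 (replicate 2 with the wild type in red, replicate 3 with the mutant in red) and 0.15 (replicates 3 and 2). Such deviations depend on one another and still hold the dye system effect. They therefore do not decide whether the replicate numbers pair the arrays. Blocks that join differently numbered arrays were not fitted, so a shared culture across numbers stays open. With the replicate block averaged, 72 were lower and 31 higher, and with the replicate block as a random effect 105 and 46. List tests were not run with the random effect, and the promoter search was not run.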

Other observations

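The tests of the MSN4 probe, of the chaperone list by dye system and scan session and of the ribosomal proteins by scan session were chosen only after the result was seen.

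The MSN4 probe was higher in the RNA labelled mutant by 1.57. Exchanged strain labels would put stress targets higher in the RNA labelled mutant, and 21 were lower and 0 higher, with 9 to 22 lower and 0 higher when 1 array was left out. A dye or scan artefact at its spots would follow the orientation, but the turned ratio was above 0 on 6 of 6 arrays. Transcript left from the disrupted locus, or signal of a related sequence at the probe, stays open because the position of the probe is not given. The probe was above background in the channel labelled mutant on 6 arrays, which shows that something hybridised there but not why the ratio was above 0.

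Heat shock and chaperone genes outside the stress target list had a median of 0.33 over 22 genes, 7 higher and 1 lower. But without either Cy array only 1 gene of all tested was higher, and BTN2, CPR6, HCH1 and HSC82 lost their calls. Their values in that fit were 0.99, 0.88, 0.95 and 0.92, against 1.05, 0.88, 0.86 and 0.88 in the full fit. The camera adjusted p was 2.25e-06 with the preset correlation alone, and the whole chaperone list gave an adjusted p of 0.446 with an estimated correlation and 0.0562 in fry. The loess had already fitted the trend with brightness on each array, so only a bias left after it was tested. Such a bias, shared by genes of like brightness, does not account for the median. It lay at percentile 100 of 10000 random lists matched on brightness. The lowest median within the dye systems and scan sessions was 0.37, so neither accounts for the direction. With 2 cultures per strain and arrays not matched to them, a difference between the particular cultures grown stays open and may be the cause, as may a response of the heat shock factor to the lack of the activators, which was not tested.

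The ribosomal protein genes had a median of 0.25. A bias left after the loess and shared by genes of like brightness is argued against in the same way, by a percentile of 100. The shift differed between the scan sessions with the preset correlation (adjusted p = 8.84e-14) and the difference was lost with an estimated correlation (adjusted p = 0.880). Scan session and biology cannot be told apart for the size of this shift, because the session of 2 arrays had a median of 0.04, and no biological explanation was tested.

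The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 104 lower genes, where the highest other split gave 39, and 1 split of the 10 reached the real count. For the higher genes the real count was 43 and the highest other 39, and again 1 split reached it. The split with 39 put both Cy arrays on the same side, so its effects were estimated from the Alexa arrays alone. With those arrays alone the real grouping gave 33 lower and 1 higher, so the counts are not like for like. In every split but the real one the strain difference could also add to the spread, so the comparison does not decide whether an arbitrary grouping gives as many calls.

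Some further genes, chosen after their values were seen, passed the threshold outside the lists. SNZ1 (-1.26, adjusted p = 0.00198) and SNO1 (-0.96, adjusted p = 0.00602), neighbouring genes of vitamin B6 synthesis, were lower, as were the metallothionein gene CRS5 (-0.99) and the stress-related transcription factor gene USV1 (-1.24). RGR1 was not above background on any array in the channel labelled mutant (fitted ratio -1.67, adjusted p = 0.0260, n = 4 arrays). Without a dye term, and with dim signal raised to the lowest detected intensity, its wild-type mean was 1.90-fold higher. An undetected spot can be brighter than that intensity, so this fold is not a lower limit.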
